A study of Mus musculus with 8 samples.

How the data were processed

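RNA from inguinal white adipose tissue of 6-week-old mice was measured in 8 libraries, 4 from floxed controls and 4 from mice with Lsd1 deleted by Adipoq-Cre. Per the series design text and the submitters' processing notes, reads were aligned with TopHat version 2 to mm10 and counted with HOMER, and changed genes were sought with edgeR and DESeq version 1.8.3. The HOMER version, the annotation, the strandedness and the scaling are not given in the sources used here. Each deposited file held 23373 rows, of which 1 had no accession and a value of 0 in all libraries. It was left out.

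The deposited values were a signal, not whole counts. In each library they were whole multiples of 1 step, from 0.442 to 0.545, within a tolerance of 0.02, for 99.98 to 100% of the values above 0. The authors therefore deposited read counts multiplied by 1 factor per library, with totals of 13999923 to 14369969. Dividing by the step recovered 25671837 to 32442724 reads per library. Even multiples up to 40 made up 54.0 to 56.2% of low values, and in control replicate 1 361 values lay at 1 step against 642 at 2 steps. A step can therefore be 1 end of a read pair, in which case counting error is larger than the recovered reads imply. The 10 highest genes held 9.26 to 12.1% of a library's total.

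Accessions were matched to symbols with a RefSeq table of GRCm38.p6 (22527) and GENCODE M21 (124). The other 721, with 1.64% of the reads, kept their accession. Where a symbol had 2 rows (12 symbols), the row with the higher total was kept. Coordinates are those of the RefSeq table, which has the same base assembly as mm10. Overlaps with other genes were taken from GENCODE M21 as overlaps of whole gene spans, introns included. Overlaps of exons were not computed. Apart from those given with a gene's result, Kdm1a, Cidea, Ppargc1a, Pparg, Hsd11b1, Cpne4 and Cd9 overlap predicted or small noncoding genes, and the ends of Elovl3 and Slc25a21 overlap Pitx3 and Pax9 over 10 and 189 bases.

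The design fixed before the data were examined was an edgeR quasi-likelihood test on counts. Because the files hold scaled values, the main test was instead limma (3.58.1) with a mean-variance trend on log2(value + 1), with genotype as the only term, on the 14591 genes with a value of at least 10 in at least 4 libraries, and with Benjamini-Hochberg adjustment. The pseudocount was 1. The edgeR (4.0.16) test on recovered reads was run as an added alternative and called 207 genes. R was 4.3.3, and files were read with Python 3.11.15 and pandas 2.3.3. List scores likewise used log2(value + 1) in place of the planned log2 CPM.

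Gene lists (33 with at least 5 tested members) were written before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move one way. With the estimated correlation 0 of 33 lists passed camera, and 3 passed fry, those of general adipocyte genes, lipolysis and UCP1-independent thermogenesis. The mixed form of fry, planned too, asks whether genes of a list move in either direction. It passed for more lists, among them thermogenic genes (adjusted p = 0.00454), neuronal genes repressed by REST (0.00109) and nerve markers (0.00109). List scores were compared by an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286. The named genes were Kdm1a, 10 genes fixed in advance, the 8 higher and 8 lower genes with the largest fold change among those past the threshold with a mean of at least 2 CPM in the higher group and non-overlapping groups, and up to 4 members of each list that passed camera and of 6 lists named in advance. Some items that the rule names are not reported here.

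Alternatives fixed in advance were other scalings (RLE, upper quartile, library totals), DESeq2 (1.42.0), the edgeR exact test, limma-voom with and without quality weights, filters, stricter thresholds, all rows as deposited, leaving out each library, leaving out the 2 controls numbered 517 and 518, and 1 surrogate variable (sva 3.50.0) or a B cell, mammary or muscle score as a covariate. Added after the data were seen were edgeR on recovered and on halved reads, TMM, pseudocounts of 0.5 and 5 for genes, the list tests with the muscle covariate, and fits with 1 knockout library. The numbers in the sample titles were not shared between genotypes, so no pairing was used. Libraries of 1 group differed by 26.6 to 143 times the sampling noise (chi-square per degree of freedom), so no pair agreed within sampling noise.

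The test was checked on simulated reads drawn from the real means, library sizes and dispersions of this comparison with 200 genes changed (14619 genes tested). It recovered 36.0% of genes changed 1.5-fold, 78.0% of those changed 2-fold, 98.0% at 4-fold and 100% at 8-fold, and 7 of its 163 calls were false. Each gene was drawn independently, so the simulated libraries lack variation shared by many genes, and these rates do not cover it.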

Results

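Inguinal white adipose tissue, the subcutaneous fat pad of the groin, was profiled by RNA sequencing in 6-week-old mice that lacked Lsd1 in adipocytes and in floxed controls. Lsd1, encoded by Kdm1a, is a histone demethylase that works in repressor and activator complexes, and the Adipoq-Cre transgene used to delete it is active in adipocytes. There were 4 control and 4 knockout libraries, all labelled as separate samples, and the labels do not state that each came from a separate mouse. P-values therefore measure the spread between these samples, which may be technical. The libraries held 25671837 to 32442724 recovered reads, with 27666408 to 29442190 in the controls. The single comparison asked which transcripts of the fat pad differ between these genotypes. No group carried Adipoq-Cre without the deletion, so an effect of the transgene cannot be told apart from loss of Lsd1. Values below are scaled read counts as the authors deposited them, and fold changes are knockout minus control on the log2(value + 1) scale, which understates changes of low genes.

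Kdm1a was lower in all 4 knockout libraries than in any control. Its scaled read counts were 699, 685, 799 and 735 in control replicates 1 to 4 and 566, 578, 547 and 581 in knockout replicates 1 to 4. The transcript fell by 22.0% (log2 fold change -0.36, SE 0.075, limma adjusted p = 0.0498, n = 4 per group). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 allows. The gene (NM_133872) lies on chromosome 4 from 136550533 to 136602787 in GRCm38.p6. It overlaps the antisense gene Luzp1 over 4241 bases, where reads cannot be assigned without strand. The labels do not say which exons were deleted, and cells other than adipocytes in the pad keep the gene. The call was lost when any 1 of the 8 libraries was left out, with log2 fold changes from -0.39 to -0.31 and limma adjusted p from 0.0593 (without knockout replicate 3) to 0.158 (without knockout replicate 2). It was also lost with library totals as the scaling, no filter, a pseudocount of 0.5 or the B cell (log2 fold change -0.42) or muscle (-0.40) score as a covariate (adjusted p 0.0501 to 0.0725), and without control replicates 1 and 2 together (-0.43, 0.114).

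**Figure D1:**
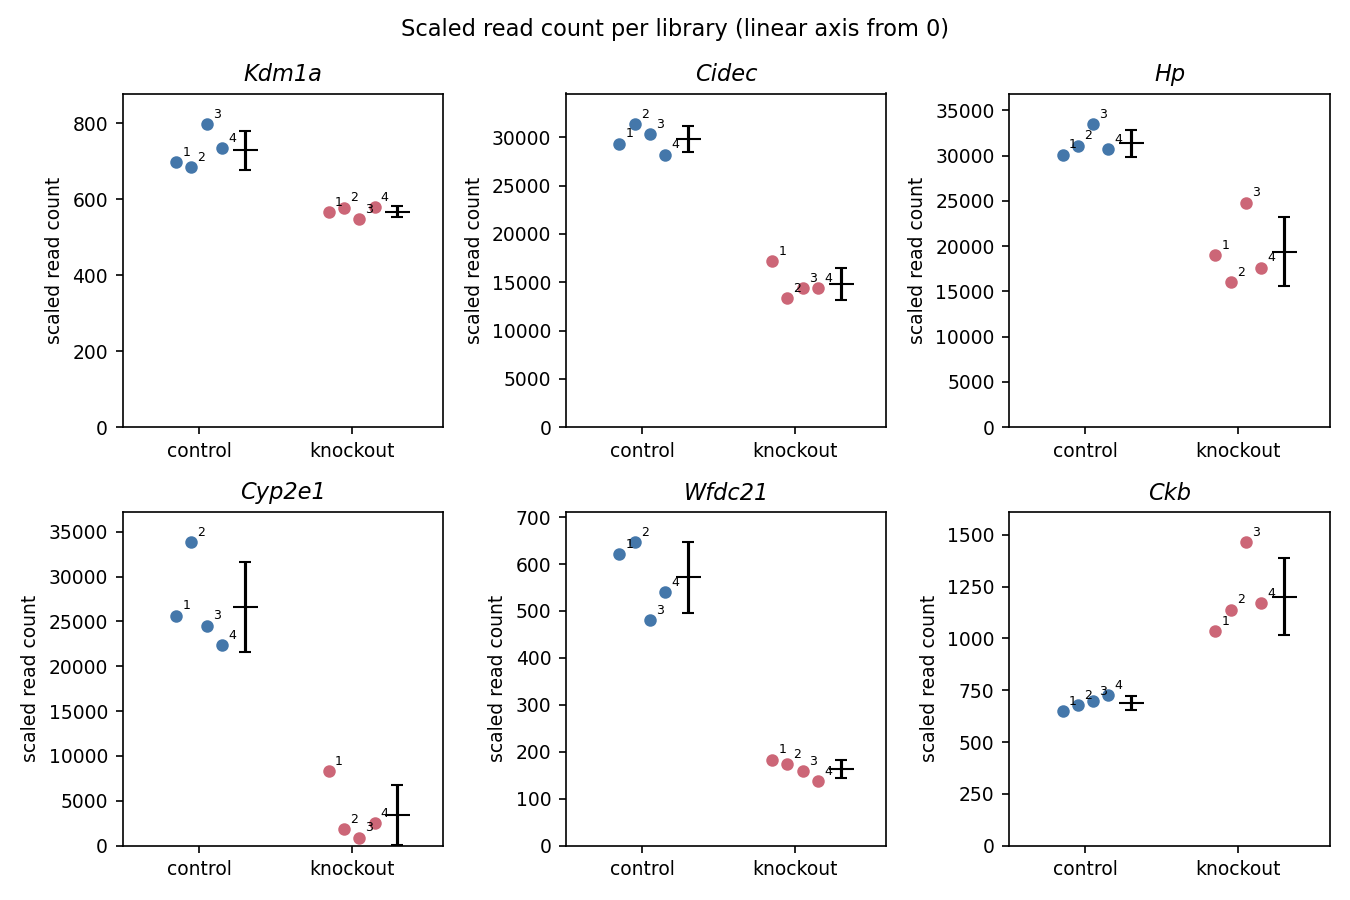
Scaled read count (linear axis from 0) of 6 genes in each of the 4 control and 4 knockout libraries, numbered by replicate, with the mean and SD as a bar. For Kdm1a the knockouts sit between 547 and 581 and the controls between 685 and 799, and for each of the 6 genes the groups do not overlap.

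More genes were higher than lower in the knockout fat pad. Of 14591 genes tested, 239 passed the threshold, 187 of them higher and 52 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was seen in 89 of the higher and 12 of the lower genes. In all 239 the groups did not overlap, as in 8.65% of all tested genes, where chance gives 2.86%. The count moved with single libraries. It was 71 without knockout replicate 4, 91 without knockout replicate 2, 135 without control replicate 1, 138 without control replicate 4 and 429 without knockout replicate 3. It was 98 without control replicates 1 and 2 together, whose sample numbers, 518 and 517, lie apart from those of the other 6 libraries.

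Among the higher genes, Syt17, a synaptotagmin-family protein, went from 0.993 ± 0.801 to 56.1 ± 21.1 scaled reads (SD, n = 4 each; log2 fold change 4.87, SE 0.40, limma adjusted p = 0.000443). Kcnc4, a voltage-gated potassium channel, went from 12.01 ± 5.65 to 259 ± 36.8 (log2 fold change 4.43, SE 0.32, adjusted p = 0.000310). Cend1, known from neuronal differentiation, went from 5.26 ± 4.58 to 107 ± 65.1 (4.39 on the log2 scale), and Cpne4, a copine, from 1.1 ± 0.835 to 41.1 ± 14.1 (4.37). Arhgap36 had a log2 fold change of 3.69 and a knockout mean of 44.4 ± 36.5. Elovl4, which elongates very long-chain fatty acids, reached 46.9 ± 17.6 from 3.603 ± 0.863 (3.32). The mitochondrial carrier gene Slc25a21 (2.96) and the urotensin receptor gene Uts2r (2.85) were higher too. These 8 genes had the largest log2 fold changes among the higher genes that met the naming rule, which asks for a minimum level in the knockout. Their control means were 0.993 to 12.01 scaled reads, so the size of the fold changes rests on small counts. The call of Cend1 was lost with limma-voom (adjusted p = 0.0731) and with the B cell covariate (log2 fold change 3.75, adjusted p = 0.0927). That of Arhgap36 was lost with the mammary (3.14, SE 0.73, adjusted p = 0.0590) and muscle (3.37, SE 0.75, adjusted p = 0.0609) covariates, where the SE was larger than in the main fit (0.57).

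The lower genes ranged widely in level. Cyp2e1, a cytochrome P450 of the endoplasmic reticulum, fell from 26590 ± 5007 to 3380 ± 3332 (log2 fold change -3.44, SE 0.54, limma adjusted p = 0.0133). Its knockout values were 8281, 1838, 901 and 2500, and the call was lost without knockout replicate 2 (adjusted p = 0.0569) or 4 (0.0596). Serpina3k, a serine protease inhibitor, fell from 107 ± 83.6 to 5.88 ± 4.45 (-3.98, adjusted p = 0.00862). It overlaps the annotated gene Serpina3m and belongs to a multigene family, so its reads are uncertain. Lctl fell from 440 ± 132 to 96.0 ± 17.5 (-2.16, adjusted p = 0.000992) and its neighbour Zwilch from 122 ± 14.2 to 47.5 ± 5.001 (-1.34, adjusted p = 0.00169). The ends of these 2 genes on chromosome 9 overlap over 975 bases on opposite strands, so their reads cannot be fully told apart. Wfdc21 fell to 163 ± 19.7 from 572 ± 75.9 (-1.80), the histone gene H4c8 to 28.7 ± 5.59 from 78.6 ± 13.96 (-1.42), and Igfals, which encodes a carrier subunit of circulating insulin-like growth factors, to 131 ± 27.8 from 350 ± 109 (-1.39). H4c8 is 1 of several near-identical histone H4 genes. The call of Igfals was lost without control replicate 1 or 2 or knockout replicate 4 (limma adjusted p = 0.0507, 0.0592 and 0.0692). Without control replicates 1 and 2 together, Cyp2e1 (log2 fold change -3.27, adjusted p = 0.134) and Igfals (-1.03, 0.139) did not pass, nor did Cyp2e1 with the B cell covariate (-3.05, 0.0724). With the B cell, mammary and muscle covariates Igfals had log2 fold changes of -1.21, -1.26 and -1.49 (adjusted p 0.0529 to 0.101) and Serpina3k of -3.58, -3.38 and -3.51 (0.0506 to 0.0529), so these calls were lost with much of the fold kept.

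**Figure D2:**
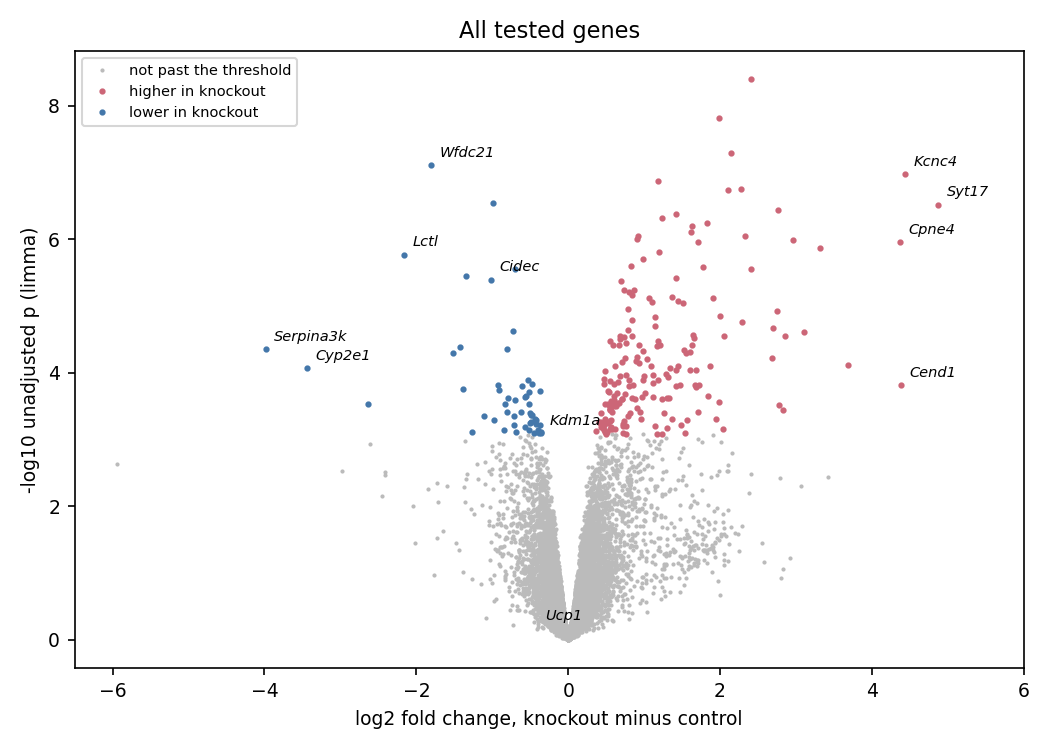
Log2 fold change (knockout minus control, x axis) against -log10 of the unadjusted limma p (y axis) for the 14591 tested genes, with 187 genes higher and 52 lower past the adjusted threshold in colour. Kdm1a lies at -0.36 beside the threshold, and Ucp1, at -0.41, lies far below it.

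Genes shared by all adipocytes were on balance lower. Of 28 tested general adipocyte genes 24 had a negative log2 fold change, with a median of -0.27 (camera with a preset correlation, adjusted p = 2.15e-07), 1 passed over all genes, and 3 were lower when adjusted over the list alone. With an estimated correlation the list's adjusted p was 0.269. The gene that passed was Cidec, which coats lipid droplets and promotes their growth, and it fell from 29815 ± 1363 to 14834 ± 1632 (log2 fold change -1.01, SE 0.11, limma adjusted p = 0.00179). Other members did not pass: Fabp4, the fatty acid carrier, was at 150241 ± 23489 in controls and 114626 ± 13273 in knockouts (-0.39, adjusted p = 0.437), Adipoq at 33402 ± 4398 and 27889 ± 2445 (-0.26, adjusted p = 0.420), and Pparg at 3434 ± 1092 and 2998 ± 371 (-0.16, adjusted p = 0.749, with the sign turned in 5 of 29 alternatives). The mean log2 value of the list was 13.3 to 13.4 in the knockouts and 13.6 to 13.8 in the controls. Skeletal muscle markers were at 11.7 or above in knockout replicates 1, 2 and 4 and at 9.82 or below in the other libraries on the same scale.

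White adipocyte-associated genes held 4 of the lower genes among 19 tested, 5 when adjusted over the list alone, and none of the higher ones. They were Wfdc21, Serpina3k, Hp and Hoxc8. Hp, the hemoglobin-binding protein haptoglobin, fell from 31361 ± 1493 to 19385 ± 3814 (-0.71, limma adjusted p = 0.0422), and the homeobox gene Hoxc8 from 711 ± 72.4 to 505 ± 42.1 (-0.49, adjusted p = 0.0404). Hoxc8 lies within the annotated span of Hoxc5. The call of Hp was lost without any 1 library except knockout replicate 3 (adjusted p 0.0776 to 0.164), and that of Hoxc8 without any 1 except control replicate 3 and knockout replicate 3 (0.0776 to 0.157). Neither passed without control replicates 1 and 2 together (Hp -0.75, adjusted p = 0.189, and Hoxc8 -0.43, 0.235) or with the B cell, mammary or muscle covariate (Hp -0.73, -0.58 and -0.49, Hoxc8 -0.42, -0.37 and -0.40, adjusted p 0.106 to 0.172 over both). Hp did not pass without a filter (0.0716), and Hoxc8 did not with RLE, upper-quartile or TMM scaling, limma-voom or edgeR on recovered or halved reads (0.0516 to 0.0677). The median of the list was 0.02 and its mean -0.28, with a camera adjusted p of 0.0987, so the list as a whole did not pass, although it was at 0.0329 without control replicate 1. Lep, the hormone leptin, was at 6614 ± 2154 in controls and 6070 ± 2497 in knockouts (-0.17, adjusted p = 0.847, with the sign turned in 5 of 29 alternatives).

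Thermogenic and beige adipocyte genes did not move in a shared direction as a list, although the list passed the mixed form of fry (adjusted p = 0.00454). Of 38 tested members 1 passed as higher and 1 as lower, with a median log2 fold change of -0.03 (camera adjusted p = 0.162, and 0.687 with an estimated correlation). Adjusted over the list alone, 2 were higher and 6 lower. Clstn3, whose locus also produces an adipocyte-specific thermogenic isoform that cannot be separated here, fell from 588 ± 108 to 209 ± 62.6 (-1.52, limma adjusted p = 0.00929). Its call was lost without control replicates 1 and 2 together (-1.39, adjusted p = 0.106) and with the B cell (-1.46, 0.0557) and muscle (-1.23, 0.0529) covariates. Eva1b went from 308 ± 28.0 to 689 ± 195 (1.12, adjusted p = 0.0156), but it is not the brown adipocyte marker once called Eva1, which is Mpzl2, so its place in the list rests on its name. Its call was lost without control replicate 1 or knockout replicate 2 or 4 (adjusted p = 0.0517, 0.0569 and 0.0678), without control replicates 1 and 2 together (1.16, adjusted p = 0.111) and with the B cell covariate (1.12, 0.0704). Ucp1, the uncoupling protein, ranged from 384 to 3189 in controls and from 167 to 4732 in knockouts, with means of 1492 ± 1248 and 1679 ± 2099, so that the mean was higher in the knockouts while the log2 fold change was negative (-0.41, SE 0.97, adjusted p = 0.886). Its sign turned in 10 of 29 alternatives, for example 0.15 with DESeq2 and 0.36 without knockout replicate 1, so its direction is not settled. Cidea (0.21), Ppargc1a (0.38) and Elovl3 (-0.40) did not pass, with adjusted p of 0.761, 0.484 and 0.867, and the sign of Elovl3 turned in 7 of 29 alternatives and that of Cidea in 1. Ppara, a nuclear receptor of fatty acid catabolism, was at 473 ± 118 and 235 ± 111 (-1.09, adjusted p = 0.125), and it passed without knockout replicate 1 (-1.37, adjusted p = 0.0246), with DESeq2, the edgeR exact test or limma-voom with quality weights, and with 1 surrogate variable or the mammary or muscle covariate (0.0113 to 0.0418). The list passed as lower without control replicate 3 (camera adjusted p = 0.00401) or knockout replicate 3 (0.0127), within a range up to 0.909.

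**Figure D3:**
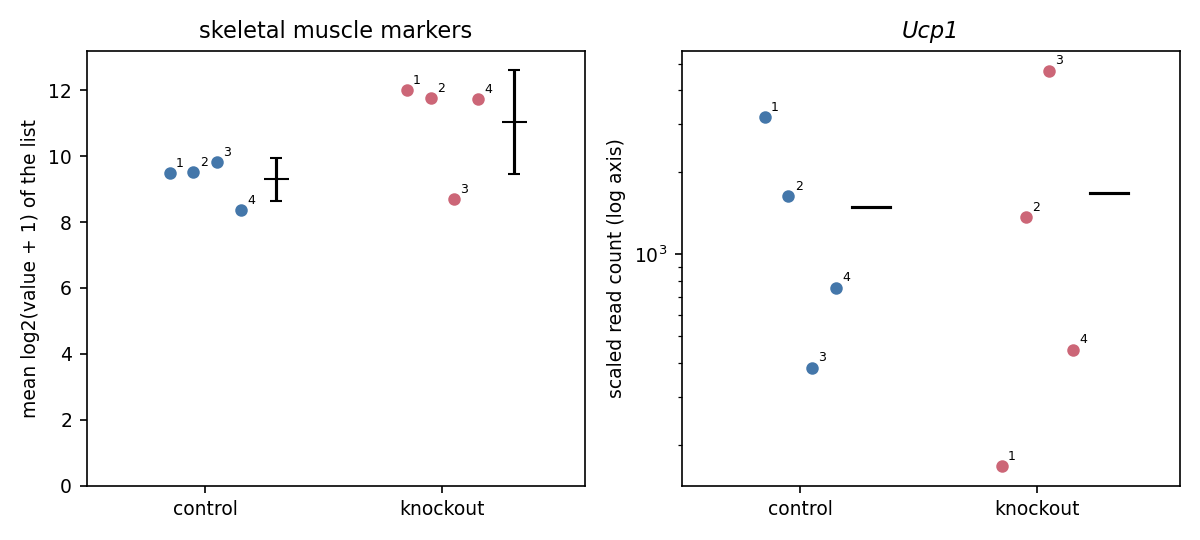
Left, mean log2(value + 1) of the 23 skeletal muscle markers in each library, with the mean and SD of each group of 4 as a bar. Right, scaled read count of Ucp1 on a log axis, with a line at each group's mean. Knockout replicates 1, 2 and 4 lie at 11.7 or above for the muscle markers, and Ucp1 spans 167 to 4732 within the knockouts.

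Of the lists of lipid and energy metabolism 6 were lower by camera with the preset correlation. Of these calls 4 were lost without control replicates 1 and 2 together. Of 29 fatty acid oxidation genes 28 had a negative fold change (median -0.24, camera adjusted p = 2.15e-07, and 0.641 with an estimated correlation), none passed over all genes, and 2 were lower when adjusted over the list alone. The list's mean log2 value was 11.5 and 11.8 in control replicates 1 and 2, 11.1 and 11.3 in control replicates 3 and 4, and 11.1 to 11.3 in the knockouts. Without control replicates 1 and 2 together its mean log2 fold change went from -0.25 to -0.021 (camera adjusted p = 0.348). The lists of lipolysis and beta-adrenergic signalling (21 genes, median -0.18, adjusted p = 0.000513, and 0.269 with an estimated correlation), the tricarboxylic acid cycle (23 genes, median -0.14, adjusted p = 0.000326, and 0.658) and fatty acid and triglyceride synthesis (24 genes, median -0.19, adjusted p = 0.00657, and 0.658) held no gene that passed, over all genes or adjusted over the list alone. Cholesterol synthesis (22 genes, median -0.16, adjusted p = 0.0419, and 0.670) held none over all genes, and 1 higher and 1 lower when adjusted over the list alone. Insulin signalling (22 genes, median -0.06, adjusted p = 0.0108, and 0.658) was lower as a list too. PPAR alpha target genes did not pass (23 genes, median -0.09, camera adjusted p = 0.0528), and 1 was higher and 2 lower when adjusted over the list alone. Their member Acot1, an acyl-CoA thioesterase with a close paralogue in Acot2, rose from 46.5 ± 16.5 to 115 ± 17.7 (1.33, limma adjusted p = 0.0243). Its call was lost without control replicate 1 or 4 or knockout replicate 1, 2 or 4 (adjusted p 0.0533 to 0.102) and with the muscle covariate, where its fold change was as large (1.38, adjusted p = 0.0647) and its SE larger (0.32 against 0.24). Without control replicates 1 and 2 together the tricarboxylic acid cycle turned upward (camera adjusted p = 0.912), and fatty acid and triglyceride synthesis (0.437) and cholesterol synthesis (0.459) were lost, while lipolysis (0.0451) and insulin signalling (0.0178) passed as lower. With the muscle covariate the tricarboxylic acid cycle was lost (0.664) and both synthesis lists turned upward (0.567 and 0.188), and muscle markers were at 11.7 or above on the log2 scale in knockout replicates 1, 2 and 4. Cholesterol synthesis was lost with RLE (0.0718) and TMM (0.0656) scaling too. Without 1 library the list calls changed for fatty acid and triglyceride synthesis (adjusted p = 0.312 without control replicate 1 and 0.252 without knockout replicate 1) and for insulin signalling (0.0831 without knockout replicate 3). Cholesterol synthesis did not pass without replicate 1 or 4 of either group (0.0833 to 0.835), and PPAR alpha targets passed as lower without control replicate 3 or 4 or knockout replicate 2 or 3 (0.00186 to 0.0269).

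Glycolysis genes were on balance higher. Of 20 tested genes 17 had a positive fold change (median 0.36, camera adjusted p = 0.00166, and 0.641 with an estimated correlation), 1 passed over all genes, and 8 higher and 2 lower passed when adjusted over the list alone. Hk1, a hexokinase, rose from 892 ± 90.5 to 1309 ± 88.4 (0.56, limma adjusted p = 0.0175). The span of its antisense gene Hk1os overlaps that of Hk1 over 23112 bases, introns included. Reads in any shared exon cannot be told apart without strand. Genes of UCP1-independent thermogenesis, which cover creatine and calcium cycling, were also higher (12 genes, median 0.32, camera adjusted p = 0.0359, and 0.368 with an estimated correlation). The brain-type creatine kinase gene Ckb rose from 688 ± 33.6 to 1202 ± 184 (0.79, adjusted p = 0.00632), and Slc25a4, the ADP/ATP carrier of heart and muscle, from 3932 ± 288 to 5431 ± 227 (0.47, adjusted p = 0.0186), and these 2 passed when adjusted over the list alone. The call of Hk1 was lost without control replicate 4 or knockout replicate 2 or 4 (adjusted p 0.0582 to 0.0786), that of Slc25a4 without replicate 1 or 4 of the controls or 2 or 4 of the knockouts (0.0536 to 0.0899), and that of the UCP1-independent list without control replicate 3 (0.215). Without control replicates 1 and 2 together, Ckb (0.74, adjusted p = 0.0776) and Hk1 (0.52, 0.0727) did not pass, nor did Hk1 with the B cell covariate (0.48, 0.0754). Slc25a4 did not pass with the muscle (0.39, adjusted p = 0.0725) or mammary (0.45, 0.0511) covariate. Both lists include genes abundant in skeletal muscle, such as Eno3 and Atp2a1, and muscle markers were at 11.7 or above on the log2 scale in knockout replicates 1, 2 and 4. With the muscle score as a covariate, a setting added after the data were seen, the adjusted p was 0.000156 for glycolysis and 0.0849 for UCP1-independent thermogenesis.

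Skeletal muscle markers differed most between libraries. Their mean log2 value was 9.48, 9.52, 9.82 and 8.35 in control replicates 1 to 4 and 11.998, 11.8, 8.69 and 11.7 in knockout replicates 1 to 4. All 23 had a positive fold change (median 1.92, camera adjusted p = 2.15e-07, and 0.641 with an estimated correlation), none passed over all genes, and the exact two-sided permutation p of the score was 0.114 (0.419 adjusted over 33 lists). The first principal component of the 500 most variable genes carried 52.3% of the variance, and 16 of its 50 leading genes were muscle markers.

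By camera with the preset correlation, markers of lymphocytes, macrophages and the interferon response were higher and those of endothelium lower. The lymphocyte and interferon calls were lost without control replicates 1 and 2 together. T and natural killer cell markers (24 genes, median 0.28, camera adjusted p = 0.000409, and 0.658 with an estimated correlation), B cell markers (21 genes, median 0.32, adjusted p = 0.00148, and 0.658) and interferon response genes (25 genes, median 0.30, adjusted p = 0.00657, and 0.658) held no gene that passed, over all genes or adjusted over the list alone. Macrophage markers (21 genes, median 0.21, adjusted p = 0.0283, and 0.641) held Cd9, a tetraspanin, which rose from 1047 ± 88.7 to 1404 ± 70.3 (0.43, limma adjusted p = 0.0328) and was the 1 gene that passed when adjusted over the list alone. Its call was lost without any 1 library except control replicate 2 and knockout replicate 3 (adjusted p 0.0651 to 0.133), without control replicates 1 and 2 together (log2 fold change 0.38, adjusted p = 0.156), with the B cell, mammary or muscle covariate (0.44, 0.37 and 0.41, adjusted p 0.0834 to 0.101), and with limma-voom (0.0533) or edgeR on recovered reads (0.0505). Without control replicates 1 and 2 together the mean log2 fold change went from 0.33 to -0.017 for B cell markers (camera adjusted p = 0.503), from 0.27 to 0.084 for T and natural killer cell markers (0.226) and from 0.26 to 0.027 for interferon response genes (0.459), while macrophage markers passed (0.0110). With the muscle covariate the calls of interferon response (0.159) and macrophage markers (0.567) were lost, and muscle markers were at 11.7 or above on the log2 scale in knockout replicates 1, 2 and 4. Endothelial markers (22 genes, median -0.16, camera adjusted p = 6.67e-05, and 0.368 with an estimated correlation) and smooth muscle and pericyte markers (18 genes, median -0.11, adjusted p = 0.0366, and 0.658) were lower, with none past the threshold over all genes. Adjusted over the list alone, 2 endothelial markers were lower, and 1 smooth muscle marker was higher and 1 lower. Early response genes of tissue handling were lower too (23 genes, median -0.33, adjusted p = 0.00148, and 0.658), with mean log2 values of 8.93 and 9.52 in control replicates 1 and 2 and 8.15 to 8.37 in the other 6 libraries. That list did not pass without control replicate 2 (camera adjusted p = 0.276), nor did B cell markers (0.0803). Interferon response was lost without replicate 2 of the controls (0.0803) or knockouts (0.222), macrophage markers without control replicate 4 or knockout replicate 1 or 4 (0.0758 to 0.128), and smooth muscle markers without control replicate 1 or 4 or knockout replicate 3 or 4 (0.0579 to 0.414). Without control replicates 1 and 2 together smooth muscle markers did not pass (0.257) and early response genes turned upward (0.503), while endothelial markers passed as lower (0.000118).

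**Figure D4:**
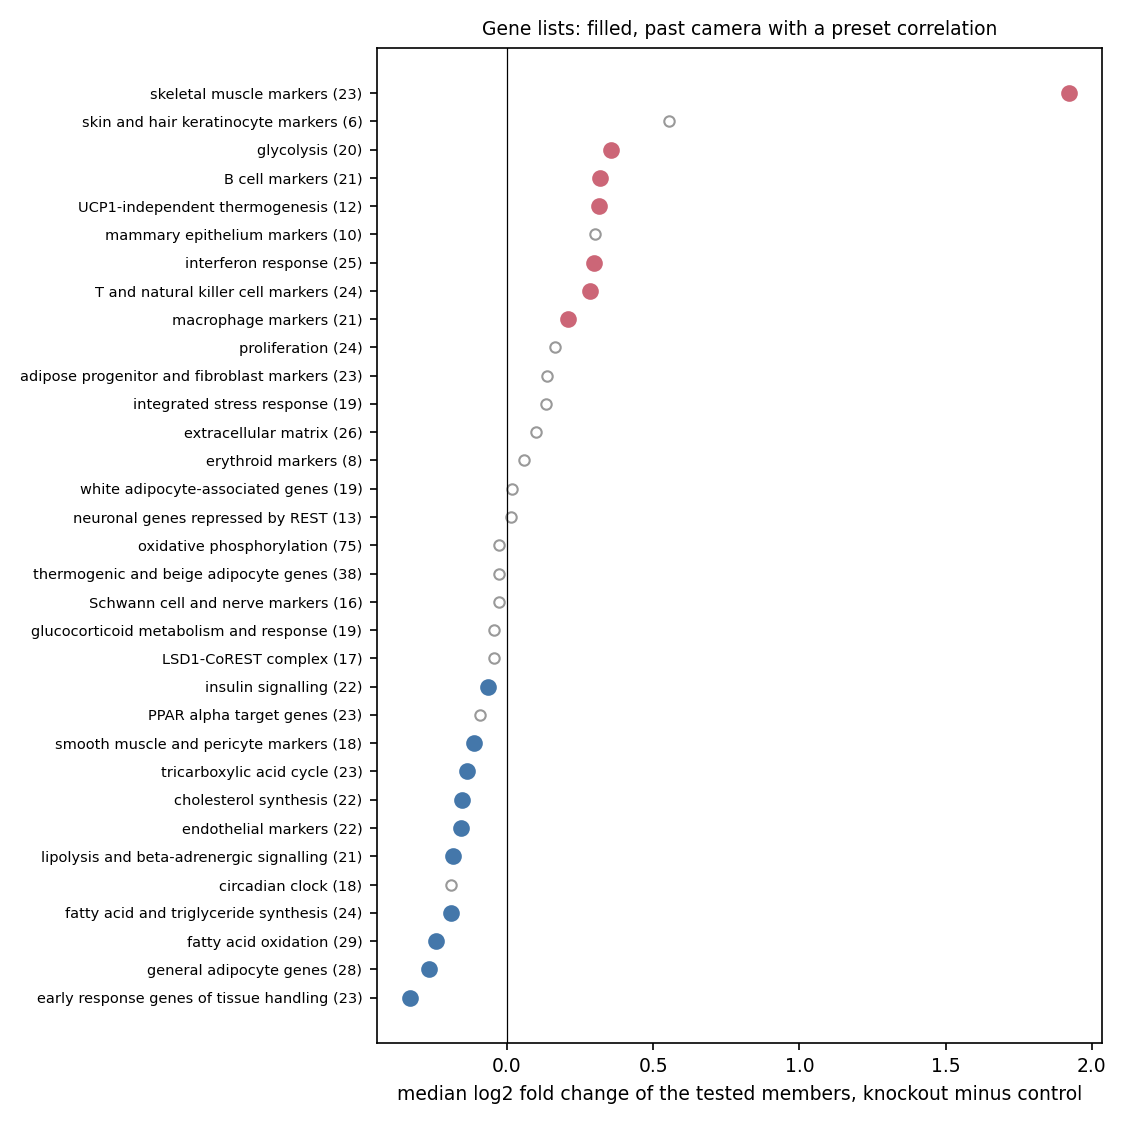
Median log2 fold change (knockout minus control) of the tested members of each of 33 lists, with the number of members in parentheses. Filled points mark the 17 lists past camera with a preset correlation, 7 higher and 10 lower, and none of the 17 passed with an estimated correlation.

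The remaining lists did not pass camera. Camera adjusted p was 0.112 for oxidative phosphorylation (75 genes, median -0.03), 0.224 for the LSD1-CoREST complex (17 genes, median -0.04) and 0.835 for neuronal genes repressed by REST (13 genes, median 0.01), in which Syp, a synaptic vesicle protein named here after its values were seen, was higher over all genes and adjusted over the list alone (0.73, limma adjusted p = 0.0432). It was 0.443 for glucocorticoid metabolism and response, where Hsd11b1, which regenerates active glucocorticoid, was at 4689 ± 758 and 5913 ± 642 (0.34, limma adjusted p = 0.270, and 0.0484 with the mammary covariate) and shares 42442 bases with the annotated gene Lamb3. It was 0.0579 for the circadian clock, 0.994 for the integrated stress response, 0.0570 for proliferation and 0.0862 for extracellular matrix. For adipose progenitor and fibroblast markers it was 0.223, for mammary epithelium 0.239, for erythroid markers 0.994, for Schwann cell and nerve markers 0.938 and for skin and hair keratinocyte markers 0.129. Among the nerve markers S100b, a calcium-binding protein of glia also named after its values were seen, was higher over all genes and adjusted over the list alone (2.76, limma adjusted p = 0.000488). Without 1 library, oxidative phosphorylation passed as lower without control replicate 3 (1.05e-05) or knockout replicate 3 (1.26e-06), the circadian clock without control replicate 3 (0.00811) or 4 (0.0422), and proliferation as higher without control replicate 1 or 3 or knockout replicate 2 (0.000977 to 0.0345). Extracellular matrix passed as higher without control replicate 2 or 4 or knockout replicate 2 or 3 (0.0108 to 0.0391), and keratinocyte markers without knockout replicate 4 (0.0289). Oxidative phosphorylation turned upward and passed without control replicates 1 and 2 together (0.00264) and with the muscle covariate (0.000496), and proliferation passed with RLE (0.0433) and TMM (0.0454) scaling.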

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

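The tests of nerve genes, of the adipocyte share and of a muscle effect in every knockout were chosen after their results had been seen. The gene fits with a muscle covariate and without the 2 controls numbered 517 and 518 were planned. The rules for reading these fits as tests were written after their results had been seen. The other tests named here were chosen before their results were seen. Of 146 groups of 4 libraries examined, 6 held a library far from the other 3, where chance gives about 1 in 20, or 7.3.

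Adipoq in control replicate 2 was at 39979, against 30754 to 31592 in the other controls. Lctl in knockout replicate 1 was at 69.8, against 103 to 106 in the other knockouts. The mean log2 value of UCP1-independent thermogenesis in knockout replicate 3 was 8.99, against 9.34 to 9.38. That of extracellular matrix in control replicate 1 was 12.11, against 12.25 to 12.27. That of skeletal muscle markers in knockout replicate 3 was 8.69, against 11.7 or above. The number of rows above 0 in knockout replicate 1 was 17690, against 17469 to 17493.

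The count of 239 genes past the threshold was set against all 35 ways to split the 8 libraries into 4 and 4. The genotype split was the 1 split that gave as many, and the highest of the others called 1 gene. A share of 1 in 35 is the smallest this test can give, so chance is not excluded. Every other split mixes the genotypes, so any difference between the groups, whatever its cause, lowers the counts of the others.

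The first pattern is the high level of muscle transcripts in knockout replicates 1, 2 and 4. Acta1 was at 45249, 38179 and 27678 scaled reads in these libraries and 2986 in knockout replicate 3, against 1982 to 8632 in controls, and Ckm was at 16479 to 29010 against 990 to 4842. Carry-over of a muscle fragment with the pad predicts that the 23 markers move in step, and their median pairwise correlation over the 8 libraries was 0.97, so carry-over may account for the pattern, although a switch of the whole programme would look alike. Of the 23 markers 3 are in another list and 21 had a control mean of at least 100. A rise was not seen in every knockout library. Knockout replicate 3, with a mean log2 value of 8.69, lay below control replicates 1 to 3 (9.48 to 9.82) and above control replicate 4 (8.35). An effect of the knockout on muscle transcripts cannot be told apart from chance placement of such fragments (exact permutation p = 0.114), because 1 library decides it.

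The second pattern is that most of the genes past the threshold were higher in the knockout. Carried-over muscle would shrink these changes once the muscle score is a covariate. The median log2 fold change of the 187 higher genes was 1.01 with it and 0.97 without, while their median SE went from 0.14 to 0.17. Of the 239 calls 138 were kept. Of the 241 genes past the threshold with the covariate, 160 were higher (66.4%, against 78.2% without). The groups of the 187 genes do not overlap, so each was above every control in knockout replicate 3 too, where muscle markers were low (8.69). Genes that follow the muscle score could hardly enter this set, so its median decides little about muscle. Carried-over nerve would raise abundant myelin genes, and the median log2 fold change of Mbp, Pmp22 and Prx was -0.0024, while S100b was at 2.76. Without the controls numbered 517 and 518 the median of the higher genes was 0.93 and their median SE 0.16, 79 calls were kept, and 85 of 98 genes past the threshold were higher. The 187 genes were also above every other control, so their median without those controls decides little either. Most genes past the threshold were still higher in both fits. Of these higher genes, 119 of the 160 with the covariate and 71 of the 85 without those controls belong to the 187. The shares therefore decide little about muscle or those controls, and both stay open as causes of the excess. The myelin values argue against nerve as the whole cause. An effect of the genotype, the Cre transgene included, stays open as a hypothesis, since it is what separates the groups.

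The third pattern is the lower level of general adipocyte genes. Dilution by muscle would move their median log2 fold change of -0.27 towards 0 under the muscle covariate, and it was -0.25 there. A smaller share of adipocytes would raise markers of every other cell type alike, but the endothelial median was -0.16 while the T cell, B cell and macrophage medians were 0.28, 0.32 and 0.21, although none of the 4 lists passed with an estimated correlation (adjusted p = 0.368, 0.658, 0.658 and 0.641). Progenitor and fibroblast markers had a positive median too (0.14), while smooth muscle and pericyte (-0.11) and nerve (-0.03) markers had negative medians. The mean log2 value of macrophage markers less that of endothelial markers was 0.37 to 0.50 in the knockouts and -0.018 to 0.25 in the controls (exact permutation p = 0.0286, and 0.0857 with T cell and 0.114 with B cell markers in their place). These lists had already been seen to move apart, so this p adds little. The opposite medians argue against a smaller share alone. However, the macrophage list lost its call with the muscle covariate (0.567), and the B cell list pointed down without the controls numbered 517 and 518 (0.503). The mean log2 value of B cell markers was highest in control replicate 3 (9.81, against 9.38 to 9.76 in the knockouts). A genotype effect within adipocytes, or a rise of immune cells alone, stays open. Whether such cells belong to the pad or came with its dissection was not tested. The general adipocyte list did not pass with an estimated correlation (adjusted p = 0.269).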

How the results depend on the processing

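The alternatives added after the data were seen were the muscle covariate for lists, edgeR on recovered and halved reads, TMM, pseudocounts of 0.5 and 5, and the fit with 1 knockout library. That library was knockout replicate 3, the one with few muscle transcripts, and the spread in that fit is taken from the controls. All others were planned. Every gene past the threshold kept its sign in every alternative that tested it. For fits that leave out libraries this was fixed in advance, because the groups of these genes do not overlap. Of the 27 named genes past the threshold, 17 passed in every fit without 1 library that tested them, and 11 passed in every alternative that tested them, the fit with 1 knockout library left aside. Of the 11, Syt17, Cpne4, Elovl4, Slc25a21 and Uts2r were tested in 24 of 29 alternatives, among them 4 of the 8 fits without 1 library. Those 4 fits each left out a control, because these genes fell below the filter without a knockout library. Cend1 and Arhgap36, among the 17, had the same gap. How far these genes depend on a single knockout library was not tested. Over the named genes other than Kdm1a and all their alternatives, 872 values kept their side and direction, 100 lost the threshold, 8 gained it and 28 changed sign, and for lists other than the thermogenic one the numbers were 352, 70, 19 and 39. All scalings gave 213 to 235 genes, with 77.7 to 81.3% of them higher. With 25671837 to 32442724 reads per library, depth limits genes read at a few reads per library. Unless stated, the cause was not tested.

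The count of 239 genes (187 higher, 52 lower) became 803 (514 and 289) with DESeq2, 672 (475 and 197) with the edgeR exact test, 598 (403 and 195) with limma-voom and quality weights, and 547 (390 and 157) with 1 surrogate variable. It became 98 (85 and 13) without the controls numbered 517 and 518 and 101 (89 and 12) with the B cell covariate. Lower genes numbered 134 with the mammary covariate and 81 with the muscle covariate. The fit with 1 knockout library, which has fewer samples, called 17 (7 and 10). At an adjusted p under 0.01 the count was 80 (69 and 11), and with an absolute log2 fold change of at least 1 it was 101 (89 and 12), as stricter thresholds must give. Without 1 library the count ran from 71 to 429 (60 to 361 higher, 11 to 79 lower).

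Kdm1a lost the threshold with library totals (-0.35), no filter (-0.36), without the controls numbered 517 and 518 (-0.43), with the B cell (-0.42) and muscle (-0.40) covariates, with a pseudocount of 0.5 (-0.36) and with 1 knockout library (-0.41). Without 1 library it ran from -0.39 to -0.31. Its adjusted p ran from 1.57e-05 to 0.198 over all alternatives.

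The 17 lists past camera became 0 with an estimated correlation, 3 with fry, 9 without the controls numbered 517 and 518, 11 with the muscle covariate and 6 with 1 knockout library, and 14 to 21 without 1 library. Lists with an exact p under 0.05 numbered 4, and 2 to 4 without 1 library. The thermogenic list pointed up without the controls numbered 517 and 518 (adjusted p = 0.290), with the muscle covariate (0.775) and with 1 knockout library (0.497), and its adjusted p ran from 0.00401 to 0.909 without 1 library.

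Genes that had not passed changed sign as follows. Ucp1 was at 0.15 with DESeq2, 0.15 with the edgeR exact test, 0.16 with edgeR on recovered reads and 0.16 on halved reads, 0.63 without the controls numbered 517 and 518, 2.04 and 1.22 with the mammary and muscle covariates and 2.09 with 1 knockout library. Elovl3 was at 0.69 without those controls, 0.26, 0.89 and 0.33 with the B cell, mammary and muscle covariates and 0.92 with 1 knockout library. Pparg was at 7.4e-05 without those controls, 0.018 and 0.082 with the B cell and mammary covariates and 0.061 with 1 knockout library. Lep was at 0.36 and 0.31 with the mammary and muscle covariates and 0.47 with 1 knockout library. Without 1 library the ranges were -1.24 to 0.36 for Ucp1, -0.018 to 0.41 for Cidea, -0.90 to 0.37 for Elovl3, -0.25 to 0.044 for Pparg and -0.38 to 0.053 for Lep.

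List directions turned, with these adjusted p. Without the controls numbered 517 and 518 they were 0.00264 for oxidative phosphorylation, 0.912 for the tricarboxylic acid cycle, 0.503 for PPAR alpha targets, early response genes and B cell markers, 0.290 for erythroid and 0.912 for nerve markers. With the muscle covariate they were 0.000496 for oxidative phosphorylation, 0.567 for fatty acid synthesis, 0.188 for cholesterol synthesis, 0.991 for REST targets, 0.883 for mammary, 0.755 for muscle and 0.872 for erythroid markers. With 1 knockout library they were 1.13e-06 for oxidative phosphorylation, 0.734 for the tricarboxylic acid cycle, 0.29997 for fatty acid synthesis, 0.0776 for cholesterol synthesis and for muscle markers, 0.963 for REST targets, 0.521 for extracellular matrix, 0.568 for progenitor, 0.583 for mammary and 0.473 for erythroid markers. With fry, nerve markers turned (0.766). Without 1 library the ranges were 1.26e-06 to 0.499 for oxidative phosphorylation, 0.618 to 0.941 for REST targets, 0.414 to 0.835 for the integrated stress response, 0.393 to 0.946 for erythroid and 0.283 to 0.843 for nerve markers.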

Other observations

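The tests of the X chromosome and the refits of branched-chain amino acid breakdown were chosen after the first result of each had been seen, and the others here before their results were seen. The genes in the next paragraph lie outside the rule for named genes and were chosen after their values were seen.

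Got2 and Got1, the mitochondrial and cytosolic aspartate aminotransferases, had log2 fold changes of 1.19 and 0.80 (limma adjusted p = 0.000327 and 0.00246), and Kyat1 of 0.83. Mapt, Map1a and Map2, which bind microtubules, were at 0.99, 1.15 and 0.99, the synaptic vesicle protein Syp at 0.73 and the ubiquitin hydrolase Uchl1 at 0.72. S100b rose from 95.2 ± 16.5 to 672 ± 209 scaled reads (SD, n = 4 each). The fatty acid transporter Slc27a1 fell from 10293 ± 3690 to 4186 ± 1066 (-1.26, adjusted p = 0.0495), and Bscl2, the seipin of lipid droplets, from 4713 ± 176 to 3470 ± 438 (-0.45, adjusted p = 0.0496). The mitochondrial carbonic anhydrase Car5b fell from 4411 ± 349 to 2216 ± 130 (-0.99, adjusted p = 0.000443). Nos3, the nitric oxide synthase of endothelium, fell from 1159 ± 82.8 to 710 ± 18.5 (-0.70, adjusted p = 0.00134).

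Hibch, Hibadh, Aldh6a1 and Hsd17b10, 4 enzymes of the breakdown of valine or isoleucine, were lower (-0.52, -0.49, -0.69 and -0.43). A hypothesis was that the other genes of branched-chain amino acid breakdown are lower too. Without these 4, 20 of 21 genes had a negative fold change, with a median of -0.31. Their unadjusted camera p was 8.00e-09, and 0.0393 with an estimated correlation. The exact permutation p of their mean was 0.0286, the smallest possible. Without the controls numbered 517 and 518 the median was -0.15 (camera p = 8.88e-05, and p = 0.0379 with an estimated correlation), and with the muscle covariate it was -0.28 (0.000129, and 0.175). The exception was Bcat1, which was higher (1.31, limma adjusted p = 0.0458). No other member passed on its own, and Dld and Echs1 are also members of lists of mitochondrial metabolism. The p-values of this list are not adjusted over lists, unlike those of the lists fixed in advance. Its hypothesis came from 4 genes that had passed in these same libraries. With an estimated correlation, lipolysis (unadjusted camera p = 0.0138), general adipocyte genes (0.0163) and endothelial markers (0.0361) had smaller p. After adjustment these were 0.269, 0.269 and 0.368.

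A hypothesis that a gene family recognised by its symbol was over-represented among the higher genes was not borne out. Over 161 families with at least 10 tested members, the smallest Fisher adjusted p was 1, and the family with the smallest unadjusted p, Map, held 3 of 44 (p = 0.0187). A family here is the letters of a symbol before its first digit or hyphen, which can pool unrelated genes. Families with fewer than 10 tested members were not examined, so an excess of small families is not excluded.

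Lctl and Zwilch are neighbours that were both lower, and a hypothesis was that genes past the threshold lie side by side more often than chance. There were 4 such pairs with the same direction, against a mean of 2.56 in 10000 random draws, of which a share of 0.255 had as many. The others were Inpp5j with Selenom, St6galnac6 with Ak1, and Gm11837 with Necab1.

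A floxed allele can carry a passenger region, but the controls were floxed too, so it need not differ between the groups. Within 10 Mb of Kdm1a on chromosome 4 there were 4 genes past the threshold among 227 tested, Kdm1a not counted (Fisher one-sided p = 0.521). Among them were Cnksr1, Tcea3 and Pafah2, higher, named after their values were seen. No excess was seen there, but with the allele floxed in both groups the test decides little. On the X chromosome 13 of 460 tested genes passed, 11 of them higher, where 7.65 would fall by chance (one-sided Fisher p = 0.0441, and 0.441 adjusted over the chromosomes). Chromosome 6 had a smaller p (19 of 730 genes, one-sided Fisher p = 0.0356, and 0.441 adjusted), so X does not stand out, and an excess there stays undecided.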
